A study of Mus musculus with 33 samples.

How the data were processed

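Mouse cells were profiled by RNA sequencing (15 libraries in 5 groups of 3) and by sequencing of methylation-enriched DNA (9 enriched libraries in 3 groups of 3, each with an input library), 33 samples in all. The RNA groups were fibroblasts grown from the tail tip of Col2.3GFP mice, induced osteoblasts (iOB) made from such fibroblasts with lentivirus, calvarial-derived osteoblasts (calvarial-OB), GFP-positive cells sorted from iOB (iOB GFP+) and GFP-positive cells sorted from bone chips. The methylation groups were fibroblast, iOB and calvarial-OB. Per the labels' protocols, virus was washed out after 24 hours, cells were split on day 3 and osteogenic medium was given from day 5; the day of harvest is not stated. RNA was purified by poly-A selection. DNA was sonicated to fragments of 100 to 350 bp, and 100 ng was enriched with methyl-CpG-binding proteins (MethylCollector Ultra). The sample titles mark the calvarial-OB RNA libraries as a second dataset, so dataset and cell type cannot be told apart in any comparison with them.

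The submitters' processing notes name STAR 2.4.2a, Bowtie2, DESeq2, R 3.2.2 and the mm9 build for all samples, without saying which tool made which values. The authors deposited a table of counts per gene symbol for the 9 fibroblast, calvarial-OB and iOB libraries. These are whole numbers for 17982 genes with at least 1 count; the counting tool, annotation and strand setting are not stated, and reads of near-identical genes such as Bglap, Bglap2 and Bglap3 could have been divided by the counting, so their values are uncertain. The columns headed OB were taken as calvarial-OB. The authors also deposited result tables for iOB against fibroblast and for iOB GFP+ against fibroblast. Per the file headers these hold a base mean (a signal averaged over normalized libraries), a log2 fold change with its standard error, a test statistic (a score formed as fold change over error), a p-value and an adjusted p-value. In the table for iOB, the base means equalled the mean size-factor-normalized counts of the 9 libraries (median ratio 1), and a refit with DESeq2's prior on fold changes differed from the deposited log2 fold changes by a median of 0.000338, so those fold changes are moderated towards 0. The libraries behind the iOB GFP+ table were not in the count table, so that comparison rests on the authors' own values. For methylation, the authors deposited a mean relative methylation score per group for 9743 windows of 100 bp that they had selected as differentially methylated; the scores have no spread per library, the selection test is not stated, how the inputs entered is not stated, and the depth is unknown.

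All computation used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with scipy 1.17.1, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The 9 libraries were fitted together with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest), with TMM normalization, genes kept by filterByExpr (13438 of 17982) and group as the only term, so that 1 estimate of the spread served 3 comparisons. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called. The common dispersion corresponded to a biological coefficient of variation of 14.8%. Values per group are CPM on TMM-scaled library sizes. The SE given with an edgeR log2 fold change is its absolute value divided by the square root of the quasi-likelihood F statistic. It is approximate where a group had few counts, and leaving out 1 library could then move the fold change by more than this SE. Where all libraries of a group had 0 counts, a fold was computed against 3 counts over the summed group and is given as a lower bound; where a group had 1 to 3 counts, the ratio is given with a 95% Clopper-Pearson interval that covers counting error only. Reads were counted without molecular identifiers, so such bounds and intervals do not cover amplification.

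Gene lists, the main tests, the alternatives and the rule for named genes were fixed before the data were examined, except where stated otherwise. The 30 lists held 584 different genes, of which 549 were measured, and 29 lists had tested members. They were tested with camera at a preset correlation of 0.01 between genes, again with an estimated correlation, and with fry, which asks whether a list's own genes move on balance one way without comparing them with other genes. For iOB GFP+ cameraPR was run on the authors' statistic at the preset correlation; an estimated correlation needs values per library. Adjustment was over lists. Members were counted at the adjusted p over all genes and again with adjustment over the list alone. The rule named, per comparison, Runx2, Sp7, Dlx5 and Atf4; the 8 higher and 8 lower called genes with the largest log2 fold change among genes at or above the median expression whose groups did not overlap; and up to 4 members per list with the smallest adjusted p together with 14 defining markers. The text describes part of that set. For methylation it named the 5 windows with the largest gain and the 5 with the largest loss in iOB. The 4 transcription factors were listed from knowledge of this study, since the labels do not name the delivered factors, and counts per gene cannot separate delivered from endogenous transcripts.

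The test was checked on counts simulated from the gene means over all 9 libraries and from their library sizes, with 200 genes changed per comparison. For iOB against fibroblast (13227 genes) it recovered 8.96% of genes changed 1.5-fold, 68.7% of those changed 2-fold and 93.9% of those changed 4-fold. The shares were 22.4%, 77.6% and 97.0% for calvarial-OB against fibroblast (13210 genes), and 25.4%, 67.2% and 98.5% for iOB against calvarial-OB (13244 genes). These simulations gave 121 to 142 calls, far fewer than the data, so the adjusted threshold was stricter and the shares may understate recovery in the data. A difference below 2-fold that was not called is still not shown to be absent.

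Methylation windows were described by group means without a test, since no value per library was in the table; the 95% Clopper-Pearson intervals on shares of windows cover the count of windows only, which are neither independent nor replicates. The planned summary of windows was a count; percentages were used for the comparison of settings after the counts had been seen. Alternatives covered another test, 2 other normalizations, no low-count filter, a fit of only the 2 groups compared, the replicate number as a block, each replicate left out, stricter thresholds, other list statistics, and other scales, thresholds and chromosomes for the windows. Overlaps between comparisons that share the fibroblast libraries were set beside 20 simulations of unchanged groups and beside the overlap of independent lists. Bone chip cells were not analysed here, because the files in hand held no values for them. Windows were not joined to genes, because the annotation in hand was of another build than mm9.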

Results

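Fibroblasts, induced osteoblasts and calvarial-derived osteoblasts were compared by poly-A RNA sequencing, with 3 libraries per group. The fibroblasts came from the tail tip of Col2.3GFP mice, in which a collagen type I promoter fragment drives green fluorescent protein in osteoblast-lineage cells. The iOB were such fibroblasts after lentiviral delivery of transcription factors and culture in osteogenic medium, and calvarial-OB were osteoblasts derived from the skull vault. The fibroblast libraries held 10642896, 7634593 and 13367273 counts, the iOB libraries 6287842, 8187715 and 5646299, and the calvarial-OB libraries 8530215, 8219411 and 15023771. The precursor ribosomal RNA Rn45s took 2.27%, 8.39% and 10.9% of the counts in the 3 fibroblast libraries and 5.08% to 5.77% in the other 6. Across genes, libraries of the same group correlated at 0.969 to 0.994. On a principal component plot the groups separated, with 60.1% of the variance on the first component and 29.7% on the second. Calvarial-OB replicate 1 stood somewhat apart, with correlations of 0.972 and 0.969 with replicates 2 and 3, against 0.987 between those.

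The comparison of iOB with fibroblasts asked how far the induction protocol had moved tail-tip fibroblasts. The labels list no group given virus or osteogenic medium alone. Effects of the delivered factors, virus, medium and time in culture therefore cannot be told apart in it. Bone matrix and mineralization genes rose in iOB. Alpl, the tissue-nonspecific alkaline phosphatase needed for mineralization, went from 36.2 ± 2.2 CPM in fibroblasts to 898 ± 153 CPM in iOB (mean ± SD, n = 3 each), a log2 fold change of 4.63 ± 0.20 (SE; edgeR adjusted p = 4.0e-08). Ibsp, which encodes bone sialoprotein, rose by 7.85 ± 0.45 on the log2 scale (edgeR adjusted p = 1.5e-07), and the osteocalcin genes Bglap and Bglap2 rose by 8.93 ± 0.39 and 8.59 ± 0.27, with counts that near-identical copies may share. Without fibroblast replicate 3 the log2 fold changes of Ibsp and Bglap were 9.12 and 10.05. Col1a1, the type I collagen chain that already stood at 18241 CPM in fibroblasts, rose by only 0.65 ± 0.20 (edgeR adjusted p = 0.018). Its call was lost without fibroblast replicate 3 (adjusted p = 0.052) or without iOB replicate 1 (adjusted p = 0.064), in a range of 3.1e-04 to 0.064 over all alternatives. Spp1, which encodes osteopontin, fell by 2.21 ± 0.17, from 2399 to 517 CPM.

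Of the factors listed as delivered, Dlx5 rose by 7.80 ± 0.19, Sp7 by 7.45 ± 0.31 and Runx2 by 2.62 ± 0.11, while Atf4 had a log2 fold change of 0.28 ± 0.15 that was not called (edgeR adjusted p = 0.15). These counts may include transcripts of the vectors. Of 33 tested osteoblast genes, 26 were higher and 2 lower in iOB (camera adjusted p = 5.5e-21; 0.023 with an estimated correlation), with Col11a2 higher by 5.24 ± 0.26. Of 19 mineralization genes, 11 were higher and 5 lower (camera adjusted p = 1.0e-06; 0.023 with an estimated correlation), among them the calcification inhibitor Mgp, which rose by 3.85 ± 0.23. The osteocyte list, genes of the cells embedded in bone, had 9 of 13 members higher and 1 lower (camera adjusted p = 0.0080; adjusted p = 0.095 with an estimated correlation). Dmp1, a matrix protein of early osteocytes, rose by 5.64 ± 0.55 and Phex, an endopeptidase of the same cells, by 4.11 ± 0.55 (6.34 for Dmp1 without fibroblast replicate 1 and 5.54 for Phex without fibroblast replicate 3). Sost, the sclerostin gene of mature osteocytes, had 2 counts in all in the iOB libraries and none in fibroblasts. Adjusted over the list alone, 27 osteoblast genes and 12 mineralization genes were higher, and the other counts of these lists were the same.

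Fibroblast genes moved both ways. Of 27, 9 were higher, 11 lower and 7 not called, or 12 higher and 11 lower adjusted over the list alone, and the list was not called (camera adjusted p = 0.16). Its median log2 fold change of 0.28 and camera's downward direction differ in sign. Fibronectin (Fn1) fell by 2.01 ± 0.11, fibrillin 1 (Fbn1) by 2.08 ± 0.11, fibulin 2 (Fbln2) by 2.91 ± 0.19, S100a4 by 1.81 ± 0.17 and Thy1 by 0.99 ± 0.15, while the fibroblast activation protein gene Fap rose by 2.56 ± 0.19. The smooth muscle actin gene Acta2 had a log2 fold change of -0.59 ± 0.21 (edgeR adjusted p = 0.040), a call that was lost when either fibroblast replicate 1 or 3 or any iOB replicate was left out and with the replicate number as a block (adjusted p = 0.051; 0.0088 to 0.17 over all alternatives). Matrix remodelling genes also moved both ways, 9 of 26 higher and 8 lower (camera adjusted p = 0.62): the collagen crosslinking enzyme gene Lox and the hydroxylase gene Plod1 fell by 1.84 ± 0.19 and 1.57 ± 0.12, while the gelatinase gene Mmp9 rose by 3.08 ± 0.50 (4.05 without fibroblast replicate 1).

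Proliferation genes were lower in iOB. None of 32 cell cycle genes was higher and 27 were lower, or 29 adjusted over the list alone, with a median log2 fold change of -1.80 (camera adjusted p = 5.3e-14; adjusted p = 0.29 with an estimated correlation). Mki67 fell by 2.20 ± 0.20 and the kinetochore genes Cenpf and Cenpe by 2.70 ± 0.25 and 2.42 ± 0.25. Of 28 genes of the amino acid response, 19 were lower and 3 higher (camera adjusted p = 3.6e-06; adjusted p = 0.26 with an estimated correlation), including Psat1 and Phgdh of serine synthesis, which fell by 1.91 ± 0.16 and 1.44 ± 0.17. Among large decreases, the lactate transporter gene Slc16a3, the mitophagy receptor gene Bnip3 and the respiratory chain gene Ndufa4l2, fell by 5.52 ± 0.40, 2.99 ± 0.34 and 2.79 ± 0.34.

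Genes of other cell types and signalling lists also moved. All 18 macrophage genes were higher in iOB, with a median log2 fold change of 5.71 (camera adjusted p = 1.1e-35; adjusted p = 0.082 with an estimated correlation). The lysosomal protease gene Ctss rose by 6.68 ± 0.34, the mannose receptor gene Mrc1 by 5.98 ± 0.34, and the complement gene C1qa by 7.35 ± 0.42. The macrophage lectin gene Clec4n, with 0 counts in fibroblasts, was at least 223-fold higher (143-fold and 132-fold without fibroblast replicate 1 and 3, where fewer counts set the bound). Of 25 interferon-response genes 23 were higher and none lower, with a median of 2.21 (camera adjusted p = 2.3e-10; adjusted p = 0.30 with an estimated correlation), among them Oas1a by 6.08 ± 0.47 (6.71 without fibroblast replicate 2) and Bst2 by 3.52 ± 0.28. Of 29 Wnt genes 19 were higher and 1 lower (camera adjusted p = 4.6e-06; adjusted p = 0.082 with an estimated correlation), including the ligand gene Wnt10b and the feedback antagonist gene Notum, which rose by 3.59 ± 0.25 and 5.87 ± 0.47 (6.59 for Notum without fibroblast replicate 1). Of 31 BMP and TGF-beta genes 14 were higher and 6 lower (camera adjusted p = 0.010; adjusted p = 0.26 with an estimated correlation), with Bmp2 higher by 5.15 ± 0.40. Of 15 adipocyte genes 12 were higher and 2 lower (camera adjusted p = 6.3e-04; adjusted p = 0.26 with an estimated correlation): Adipoq, the adiponectin gene, was at least 128-fold higher (82.6-fold and 76.4-fold without fibroblast replicate 1 and 3) and the fat-cell regulator Pparg rose by 1.17 ± 0.29. Small lists of osteoclast genes (5 of 7 higher) and keratinocyte genes (3 of 6 higher) were called as well, each with an adjusted p of 0.24 with an estimated correlation; the keratinocyte call was also lost with the replicate number as a block (camera adjusted p = 0.053). Adjusted over the list alone, 20 Wnt genes and 6 osteoclast genes were higher, 7 BMP and TGF-beta genes were lower, and the other counts of these lists were the same.

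In all, 5820 of 13438 tested genes differed between iOB and fibroblasts, 3055 higher and 2765 lower, and 2581 differed by at least 2-fold, 1857 of them higher and 724 lower. Libraries of the groups did not overlap for 63.0% of tested genes, where chance gives 10%. Of the 29 lists 13 were called at the preset correlation and 3 with an estimated one: the listed factors, osteoblast and mineralization. These 3 are not separate findings, since the osteoblast and mineralization lists share genes and the counts of the factors may include vector transcripts. The largest fry adjusted p among these 13 was 0.0020.

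**Figure D1:**
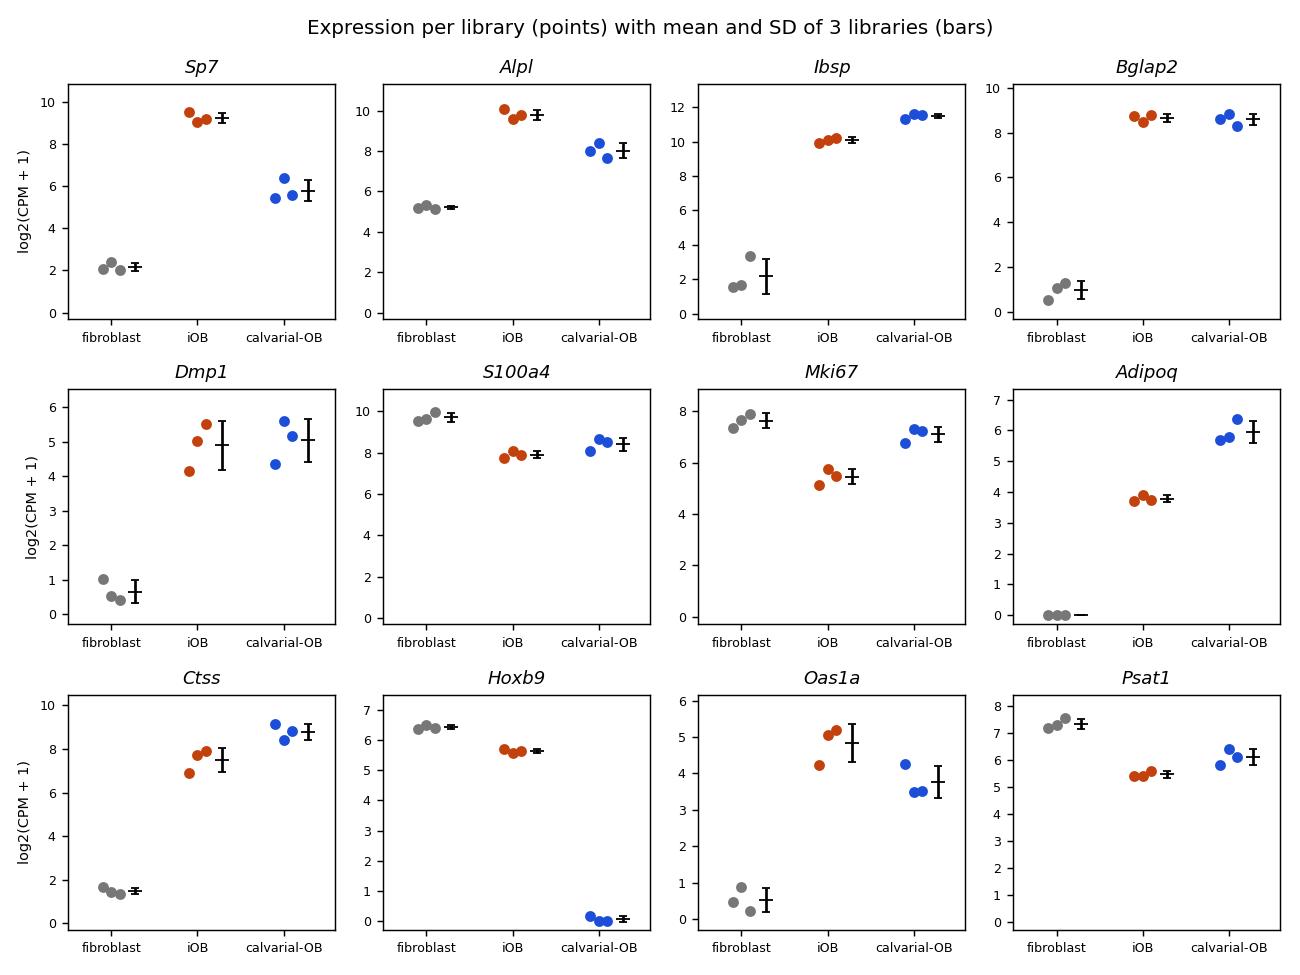
Expression of 12 genes in each library, as log2(CPM + 1) on the vertical axis, for fibroblast, iOB and calvarial-OB libraries on the horizontal axis; points are single libraries, and the bars beside them show the mean and SD of 3. Alpl, Ibsp, Bglap2 and Dmp1 are higher in both osteoblast groups, Hoxb9 is near 0 in calvarial-OB alone, and Adipoq is 0 in all 3 fibroblast libraries.

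Calvarial-OB served as the reference for osteoblasts grown from bone. Against fibroblasts they too had high bone genes: Ibsp rose by 9.27 ± 0.47 (edgeR adjusted p = 3.6e-08; 10.50 without fibroblast replicate 3), Bglap2 by 8.52 ± 0.27, Panx3, a channel gene of maturing osteoblasts, by 8.22 ± 0.35, Alpl by 2.86 ± 0.19 and Col1a1 by 1.46 ± 0.20, while Spp1 fell by 2.22 ± 0.17. Of 33 osteoblast genes 28 were higher and 2 lower, and of 19 mineralization genes 13 were higher and 3 lower (adjusted p = 0.027 for each with an estimated correlation). Sp7 rose by 4.04 ± 0.28, Dlx5 by 4.02 ± 0.20 and Runx2 by 0.63 ± 0.11, and Atf4 had a log2 fold change of -0.11 ± 0.15 (edgeR adjusted p = 0.56). The osteocyte genes Sost, Mepe and Dkk1, with 0 counts in fibroblasts, were at least 124-fold, 111-fold and 133-fold higher. Sost had 261, 48 and 89 counts in the 3 calvarial-OB libraries, and its bound was 57.7-fold without replicate 1 and 186-fold without replicate 3. Without fibroblast replicate 1 the bounds of these genes were 79.8-fold, 71.5-fold and 85.6-fold, and without fibroblast replicate 3 they were 73.8-fold, 66.2-fold and 79.1-fold. The osteocyte list had 7 of 13 members higher and 3 lower, and the list of the 4 factors 3 higher (adjusted p = 0.14 for each with an estimated correlation).

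Position genes differed between the skull and tail cells. Of 18 posterior Hox genes, which pattern the trunk, limbs and tail, 17 were lower in calvarial-OB and 1 higher, with a median log2 fold change of -6.46 when genes without counts are set at their bound (adjusted p = 0.027 with an estimated correlation). Hoxb9 had 2521 counts in fibroblasts and 1 in calvarial-OB, a ratio of 2696 (95% interval 483 to 106520), and Hoxb13 had 1885 and 2, a ratio of 1008 (279 to 8328). Without calvarial-OB replicate 1 Hoxb9 was at least 665-fold lower, and without replicate 3 its ratio was 1393 and Hoxb13 was at least 347-fold lower. Of 9 anterior Hox genes 6 were lower and none higher, or 1 higher adjusted over the list alone (adjusted p = 0.27 with an estimated correlation); Hoxb3 fell by 3.00 ± 0.26. Of 19 cranial mesenchyme genes 12 were higher and 2 lower (camera adjusted p = 2.0e-04; adjusted p = 0.14 with an estimated correlation). Six2 had 1071 counts against 1 in fibroblasts, a ratio of 1002 (95% interval 179 to 39597; 644 without fibroblast replicate 1 and at least 199-fold without replicate 3), and Alx4 rose by 2.33 ± 0.17.

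Adipocyte and macrophage genes were high in calvarial-OB. All 15 adipocyte genes were higher, with a median log2 fold change of 3.53 (adjusted p = 0.027 with an estimated correlation). Adipsin (Cfd) and Adipoq, absent from the fibroblast counts, were at least 844-fold and 657-fold higher (542-fold and 422-fold without fibroblast replicate 1, 501-fold and 391-fold without replicate 3), and Pparg rose by 3.38 ± 0.26. All 18 macrophage genes were higher, with a median of 6.75 (camera adjusted p = 5.2e-31; adjusted p = 0.0996 with an estimated correlation), among them Ctss by 7.95 ± 0.35 and C1qb by 9.49 ± 0.49. Fn1, Fbn1 and S100a4 fell by 2.20 ± 0.11, 1.84 ± 0.11 and 1.29 ± 0.16, the fibroblast list as a whole had 11 members higher and 9 lower (camera adjusted p = 0.46), and Mfap4, of the elastic fibre microfibrils, rose by 7.97 ± 0.47. Thy1 had a log2 fold change of 0.27 ± 0.14 (edgeR adjusted p = 0.13), which was called only without fibroblast replicate 3 (adjusted p = 0.047; up to 0.52 over all alternatives). Of 28 amino acid response genes 21 were lower and 3 higher (camera adjusted p = 1.2e-05; adjusted p = 0.27 with an estimated correlation). Trib3 fell by 3.51 ± 0.30 and Asns fell by 1.69 ± 0.14. Cell cycle genes were mostly not called (2 higher, 10 lower, 20 neither; 2 and 6 adjusted over the list alone), and Mki67 fell by 0.54 ± 0.19 (edgeR adjusted p = 0.028), a call lost without fibroblast replicate 2 or 3 or calvarial-OB replicate 1 and with upper-quartile normalization (adjusted p 0.0023 to 0.12 over all alternatives).

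Lists of collagens (16 of 29 higher, 10 lower), chondrocyte genes (12 of 20 higher, 5 lower), osteoclast genes (5 of 7 higher) and neural genes (5 of 8 higher, 1 lower) were also called at the preset correlation, with adjusted p values of 0.38, 0.31, 0.14 and 0.14 with an estimated correlation. For the lists named in this comparison, counts adjusted over the list alone were the same except where given. In all 7494 genes differed between calvarial-OB and fibroblasts, 3817 higher and 3677 lower (4397 and 3166 with upper-quartile normalization), and 3265 by at least 2-fold, 2019 of them higher and 1246 lower. Groups did not overlap for 60.5% of tested genes (10% by chance). Of the 29 lists 14 were called at the preset correlation and 4 with an estimated one; the largest fry adjusted p among these 14 was 0.0011.

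Setting iOB beside calvarial-OB asked where induced and native osteoblast cultures differed. Alpl was higher in iOB, by 1.77 ± 0.18 on the log2 scale (edgeR adjusted p = 9.7e-06), and several late osteoblast and osteocyte genes were lower: Panx3 fell by 2.35 ± 0.22, Ifitm5, a gene of mineralizing osteoblasts, by 4.32 ± 0.32, Phex by 3.03 ± 0.33 and Mepe by 4.96 ± 0.45 (log2 fold change -6.12 without iOB replicate 2). Sost had 398 counts in calvarial-OB and 2 in iOB, a ratio of 134 (95% interval 36.9 to 1113), or 62.5 without calvarial-OB replicate 1 and 202 without replicate 3. The osteocyte list as a whole was balanced, with 6 of 13 genes higher in iOB and 6 lower (camera adjusted p = 0.78), and of 19 mineralization genes 6 were higher and 9 lower (camera adjusted p = 0.21). Ibsp fell by 1.41 ± 0.32 (edgeR adjusted p = 0.0034; 0.063 with DESeq2, within a range of 3.5e-05 to 0.063 over all alternatives) and Col1a1 by 0.81 ± 0.20 (edgeR adjusted p = 0.0049). Bglap2, Dmp1 and Spp1 had log2 fold changes of 0.07 ± 0.17, -0.13 ± 0.35 and 0.00 ± 0.16 that were not called. Bglap, at 0.51 ± 0.25, was not called either (edgeR adjusted p = 0.11), except in a fit of these 2 groups alone (adjusted p = 0.023; up to 0.39 over all alternatives). Of 33 osteoblast genes 6 were higher in iOB and 18 lower, with a median of -0.80 (camera adjusted p = 0.0012; adjusted p = 0.33 with an estimated correlation).

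The 4 listed factors were all higher in iOB, Dlx5 by 3.78 ± 0.13, Sp7 by 3.41 ± 0.24, Runx2 by 1.99 ± 0.11 and Atf4 by 0.39 ± 0.15 (edgeR adjusted p = 0.049), as a list with an adjusted p of 0.035 with an estimated correlation. The call of Atf4 was lost without calvarial-OB replicate 2 or 3 or iOB replicate 1, with the replicate number as a block (adjusted p = 0.069), with upper-quartile normalization and in a fit of these 2 groups alone (adjusted p 0.031 to 0.27 over all alternatives). Of 18 posterior Hox genes 17 were higher in iOB and none lower, with a median of 6.33 at the bounds (adjusted p = 0.035 with an estimated correlation). Hoxb9 stood at 85.4 ± 4.2 CPM in fibroblasts, 49.2 ± 2.3 in iOB and 0.040 ± 0.070 in calvarial-OB (SD, n = 3 each), and Hoxc12, with 0 counts in calvarial-OB, was at least 208-fold higher in iOB (107-fold without calvarial-OB replicate 3). Of 9 anterior Hox genes 6 were higher and 1 lower (camera adjusted p = 0.0053; adjusted p = 0.31 with an estimated correlation). Cranial mesenchyme genes were the reverse, with 15 of 19 lower and 2 higher, or 16 lower adjusted over the list alone (camera adjusted p = 2.0e-06; adjusted p = 0.064 with an estimated correlation). Six2, with 0 counts in iOB, was at least 241-fold lower there (143-fold without iOB replicate 2).

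All 15 adipocyte genes were lower in iOB than in calvarial-OB, with a median log2 fold change of -2.24 (adjusted p = 0.046 with an estimated correlation): Plin1 and Fabp4, of the lipid droplet and of fatty acid transport, fell by 4.87 ± 0.24 and 4.72 ± 0.28. Cell cycle genes were lower, 28 of 32 with none higher and a median of -1.43 (camera adjusted p = 5.3e-10; adjusted p = 0.35 with an estimated correlation), and Mki67 fell by 1.66 ± 0.20. Interferon-response genes were higher, 22 of 25 with none lower and a median of 1.46 (camera adjusted p = 1.2e-07; adjusted p = 0.35 with an estimated correlation). Of 18 macrophage genes 9 were lower in iOB and none higher, with a median of -0.84 (camera adjusted p = 0.0053; adjusted p = 0.57 with an estimated correlation; fry adjusted p = 0.058). Fibroblast genes were mostly lower, 15 of 27 with 4 higher, or 17 and 5 adjusted over the list alone (camera adjusted p = 0.0053; adjusted p = 0.33 with an estimated correlation). S100a4 fell by 0.52 ± 0.16 (edgeR adjusted p = 0.019), a call lost without calvarial-OB replicate 2 or 3 or iOB replicate 1 or 3 (adjusted p 0.0018 to 0.088 over all alternatives), and Acta2, at -0.34 ± 0.21, was called only without calvarial-OB replicate 1 (adjusted p = 0.012; up to 0.63 over all alternatives).

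Of 29 Wnt genes 13 were higher in iOB and 6 lower, or 14 and 6 adjusted over the list alone (camera adjusted p = 0.013; adjusted p = 0.31 with an estimated correlation), with the antagonist gene Dkk2 and the ligand gene Wnt5a higher by 2.49 ± 0.18 and 2.12 ± 0.15. Of 31 BMP and TGF-beta genes 19 were higher and 6 lower (camera adjusted p = 0.038; adjusted p = 0.34 with an estimated correlation). The imprinted, fetally expressed genes H19 and Igf2 were lower in iOB, where H19 fell by 6.25 ± 0.21 and Igf2 fell by 4.93 ± 0.15 relative to calvarial-OB. The granzyme gene Gzme rose by 7.75 ± 0.21 (8.36 without calvarial-OB replicate 3), and Gzmd, another, had 1754 counts in iOB and 1 in calvarial-OB, a ratio of 2599 (95% interval 466 to 102730; at least 448-fold without calvarial-OB replicate 3). In all 6561 genes differed, 3317 higher and 3244 lower in iOB, a balance that turned with upper-quartile normalization (2912 higher and 3789 lower), and 2607 differed by at least 2-fold, 1324 of them higher and 1283 lower. Groups did not overlap for 55.5% of tested genes (10% by chance). Of the 29 lists 12 were called at the preset correlation and 3 with an estimated one. For the lists named in this comparison, counts adjusted over the list alone were the same except where given. Dataset and cell type cannot be told apart here, nor can sex. Xist had 341, 186 and 2211 counts in calvarial-OB and at most 2 in any other library, and the Y-linked gene Ddx3y was expressed in all 9.

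**Figure D2:**
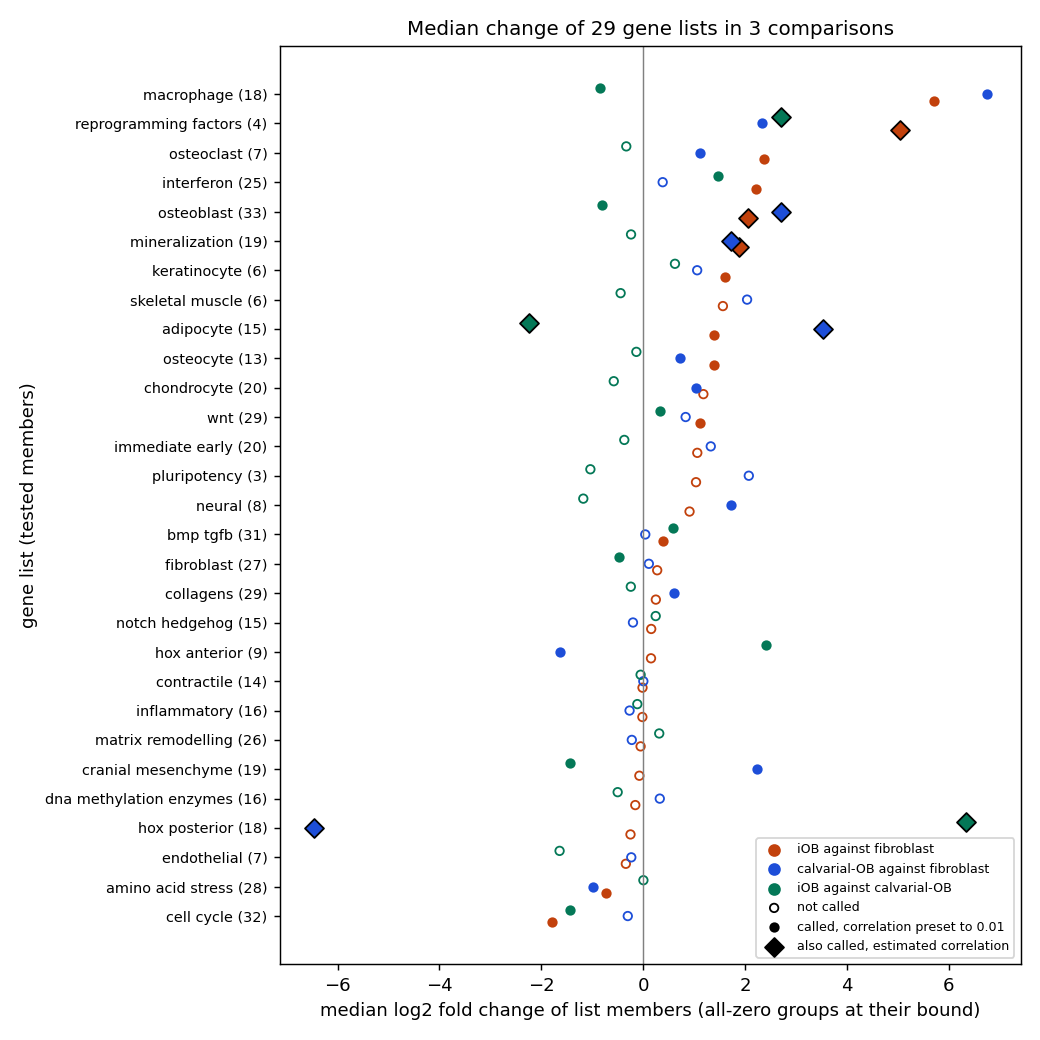
Median log2 fold change of the tested members of 29 gene lists (horizontal axis), with the list and its number of tested members on the vertical axis, in 3 comparisons marked by colour; open circles were not called, filled circles were called by camera at a correlation preset to 0.01, and diamonds were called with an estimated correlation as well. Osteoblast and mineralization lists are diamonds on the right in both comparisons with fibroblasts, and posterior Hox genes lie at -6.46 for calvarial-OB against fibroblast and 6.33 for iOB against calvarial-OB.

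Genes called in the same direction against fibroblasts in both osteoblast groups numbered 3631, of which 1959 were higher and 1672 lower; independent lists would share 868 and 757. Another 455 were called in opposite directions. Fold changes of the 2 comparisons had a covariance of 1.63 and a correlation across genes of 0.692, with genes not being independent replicates. In 20 simulations all 9 libraries were redrawn from the fibroblast means, so that no group was changed and both comparisons shared the redrawn controls. The covariance averaged 0.0552, the correlation 0.455, and no gene was called in both. Without changed genes hardly any call could arise, so the absence of joint calls does not measure how shared controls add to an overlap. The 3 fibroblast libraries are too few to be divided between the comparisons, so part of the excess over independent lists may come from shared controls. Of 2019 genes called and at least 2-fold higher in calvarial-OB, 1439 were also higher in iOB, and iOB had a median of 0.710 of the calvarial-OB log2 change. Of 1246 at least 2-fold lower, 669 were also lower in iOB, with a median fraction of 0.344. In direct comparison 1262 and 995 of these genes still differed between iOB and calvarial-OB. The genes were selected on the calvarial-OB change and both changes share the fibroblast libraries, so both fractions are descriptive.

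Sorting for the Col2.3GFP reporter asked what the reporter-positive cells of the iOB cultures expressed. In the authors' table for iOB GFP+ against fibroblast, most bone genes had larger fold changes than in the authors' table for unsorted iOB: 9.52 and 5.13 on the log2 scale for Col11a2, 10.19 and 6.54 for Ibsp, 3.44 and 0.67 for Col1a1, and 8.67 and 4.83 for Dmp1. Of 33 osteoblast genes 4 had a lower log2 fold change in GFP+ cells than in unsorted iOB. The unsorted values are moderated towards 0, which was not shown for the GFP+ values. Part of the differences between the 2 tables may therefore come from moderation. The cells were sorted on a collagen type I promoter fragment, so the larger change of Col1a1 may be set by the sort. Sost had a log2 fold change of 6.21 in GFP+ cells (authors' adjusted p = 4.2e-17) and Spp1 one of 0.47 (authors' adjusted p = 0.26), against -2.16 in unsorted iOB. Of 33 osteoblast genes 29 were higher in GFP+ cells, or 30 adjusted over the list alone, and none lower, with a median of 3.87 against 2.06 in unsorted iOB (cameraPR adjusted p = 1.2e-43 for GFP+ cells). Sp7, Dlx5, Runx2 and Atf4 were higher by 7.94, 7.17, 3.60 and 1.08 on the log2 scale (cameraPR adjusted p = 1.8e-32). Mineralization genes had 13 of 19 higher and 3 lower (cameraPR adjusted p = 2.4e-15), and osteocyte genes 10 of 15 higher and 2 lower (cameraPR adjusted p = 2.2e-04).

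Fibroblast and contractile genes were lower in GFP+ cells. Of 27 fibroblast genes 15 were lower and 4 higher, or 16 and 5 adjusted over the list alone, and 3 had no p, with a median of -1.32 against 0.30 in unsorted iOB (cameraPR adjusted p = 3.7e-04). Fbln2, S100a4 and Thy1 had log2 fold changes of -5.18, -3.66 and -3.13. Of 14 contractile genes 9 were lower and 2 higher, or 10 and 2 adjusted over the list alone (cameraPR adjusted p = 2.8e-04), with Acta2 at -2.36. Of 32 cell cycle genes 30 were lower (cameraPR adjusted p = 5.9e-19). Amino acid response genes, mostly lower in unsorted iOB, were not called as a list in GFP+ cells (cameraPR adjusted p = 0.54). Of 28, 10 were higher and 6 lower, or 11 and 6 adjusted over the list alone. Their median was 0.14 against -0.71 in unsorted iOB, and only 2 members had a lower log2 fold change in GFP+ cells than in unsorted iOB. Of 21 inflammatory genes 6 were lower, 6 not called and 9 without a p, so that no call was possible for those 9 (cameraPR adjusted p = 0.012). In the fibroblast libraries with counts replicate 1 stood apart on some of these, with 5185, 488 and 1138 counts of Ccl2 and 831, 1 and 3 of Saa3 in replicates 1 to 3, genes chosen after their values were seen. Of 25 interferon genes 20 were higher and 2 lower, or 20 and 3 adjusted over the list alone (cameraPR adjusted p = 2.2e-09). Immediate early genes, which respond to handling such as dissociation and sorting, had 15 of 20 higher and 1 lower (cameraPR adjusted p = 4.7e-07). Their median was 1.65 against 0.95 in unsorted iOB. In the edgeR comparisons of unsorted iOB and of calvarial-OB with fibroblasts, 10 and 12 of 20 were higher and 2 lower in each. An effect of sorting was not tested. Wnt genes (13 of 29 higher, 6 lower) and BMP and TGF-beta genes (11 of 31 higher, 7 lower, or 11 and 8 adjusted over the list alone) were called too, with cameraPR adjusted p values of 3.6e-06 and 0.016.

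Macrophage genes had smaller fold changes in GFP+ cells than in unsorted iOB in all 18 cases, with a median difference of -1.72, and 17 of the 18 had no p in the GFP+ table, which lacked a p for 2.13% of its 17737 genes. Their standard errors were 0.622 to 1.08 there and 0.273 to 0.587 in the iOB table, and moderation towards 0, shown here for the iOB table only, acts more where errors are larger. Why the p values of these 17 genes are missing is not stated. Without values per library it cannot be told whether single libraries set their fold changes, so the difference of -1.72 is descriptive. Ctss had log2 fold changes of 3.76 in GFP+ cells and 6.42 in unsorted iOB, and Cd68 of 3.13 and 4.52. In all the authors' adjusted p was below 0.05 for 7424 genes, 3877 higher and 3547 lower, and 12 of 30 lists were called, 8 higher and 4 lower. Fold changes of GFP+ and unsorted iOB correlated at 0.808 across 17285 genes, 3901 genes were called in the same direction in both (2014 higher and 1887 lower, against 707 and 552 for independent lists) and 69 in opposite directions. Both tables rest on fibroblast controls, which may account for part of this overlap, and no value for unchanged groups was computed for it. They were normalized separately, and the difference between sorted and unsorted cells was not tested.

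**Figure D3:**
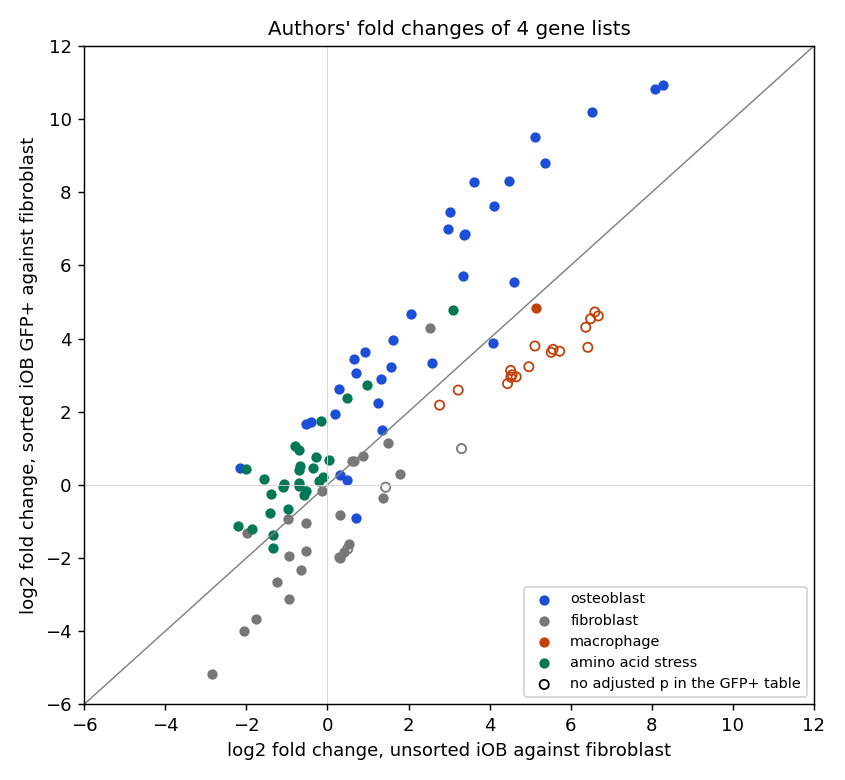
The authors' log2 fold changes against fibroblast for members of 4 gene lists, in unsorted iOB (horizontal axis) and in sorted iOB GFP+ cells (vertical axis), with the line of equal values; open points have no adjusted p in the GFP+ table. All 18 macrophage genes lie under the line, while most osteoblast genes, with a median of 3.87 in GFP+ cells and 2.06 in unsorted iOB, lie above it.

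DNA methylation was compared in 9743 windows of 100 bp on mm9 that the authors had selected. The score was lower in iOB than in fibroblasts in 8407 windows (86.3%) and higher in 1221, and lower in calvarial-OB in 7548 (77.5%) and higher in 1798. On the autosomes, with 7753 windows, the mean score was 0.543 in fibroblasts, 0.251 in calvarial-OB and 0.0055 in iOB, and iOB had a score of exactly 0 in 98.4% of windows. On the X chromosome, with 1852 windows, the means were 0.182, 0.141 and 0.224, and 1148 windows were higher in iOB than in fibroblasts while 602 were lower. Thus 94.0% of all windows that gained score in iOB lay on X (95% interval 92.5 to 95.3), against 19.01% of all windows and 7.16% of those that lost score. Windows that gained score in calvarial-OB also lay on X more often, at 43.9% (95% interval 41.6 to 46.2). The calvarial-OB RNA libraries were those with 186 to 2211 Xist counts, and whether the methylation samples came from the same cultures is not stated. Of the 929 windows with a fibroblast score of 0, 906 were on X. All 138 windows on the Y chromosome had an iOB score of 0.

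The iOB score was nearer to calvarial-OB than to fibroblast in 7998 windows (82.1%; 95% interval 81.3 to 82.8), in 87.2% of autosomal windows and in 59.99% of X windows. This nearness mostly meant that iOB lay beyond calvarial-OB, as iOB scores fell strictly between the other groups in only 26 windows and the median change in iOB was 1.74 times that in calvarial-OB. Among windows with an iOB score above 0, 54.0% were nearer to calvarial-OB. The 5 largest gains in iOB were all on X, at 97963401 to 97963500 (score 0 in fibroblasts, 0.705 in iOB and 0 in calvarial-OB), 49967001 to 49967100 (0, 0.635 and 0), 97963201 to 97963300 (0, 0.635 and 0), 154480601 to 154480700 (0, 0.63 and 0.13) and 136812101 to 136812200 (0, 0.62 and 0.095). The largest losses were at 83120601 to 83120700 on chromosome 7 (0.807 in fibroblasts, 0 in iOB and 0.39 in calvarial-OB), at 90233801 to 90233900 on chromosome 17 (0.77, 0 and 0.305), at 152301 to 152400 on 8_random (0.77, 0 and 0.27), at 16664501 to 16664600 on chromosome 10 (0.76, 0 and 0.34) and at 12947101 to 12947200 on chromosome 6 (0.76, 0 and 0.305). Genes at these positions were not analysed here. The windows were selected on these samples, the group means carry no replicate spread, and the iOB and calvarial-OB means moved in steps of a mean of 2 values although 3 libraries are listed per group, so no difference was tested.

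**Figure D4:**
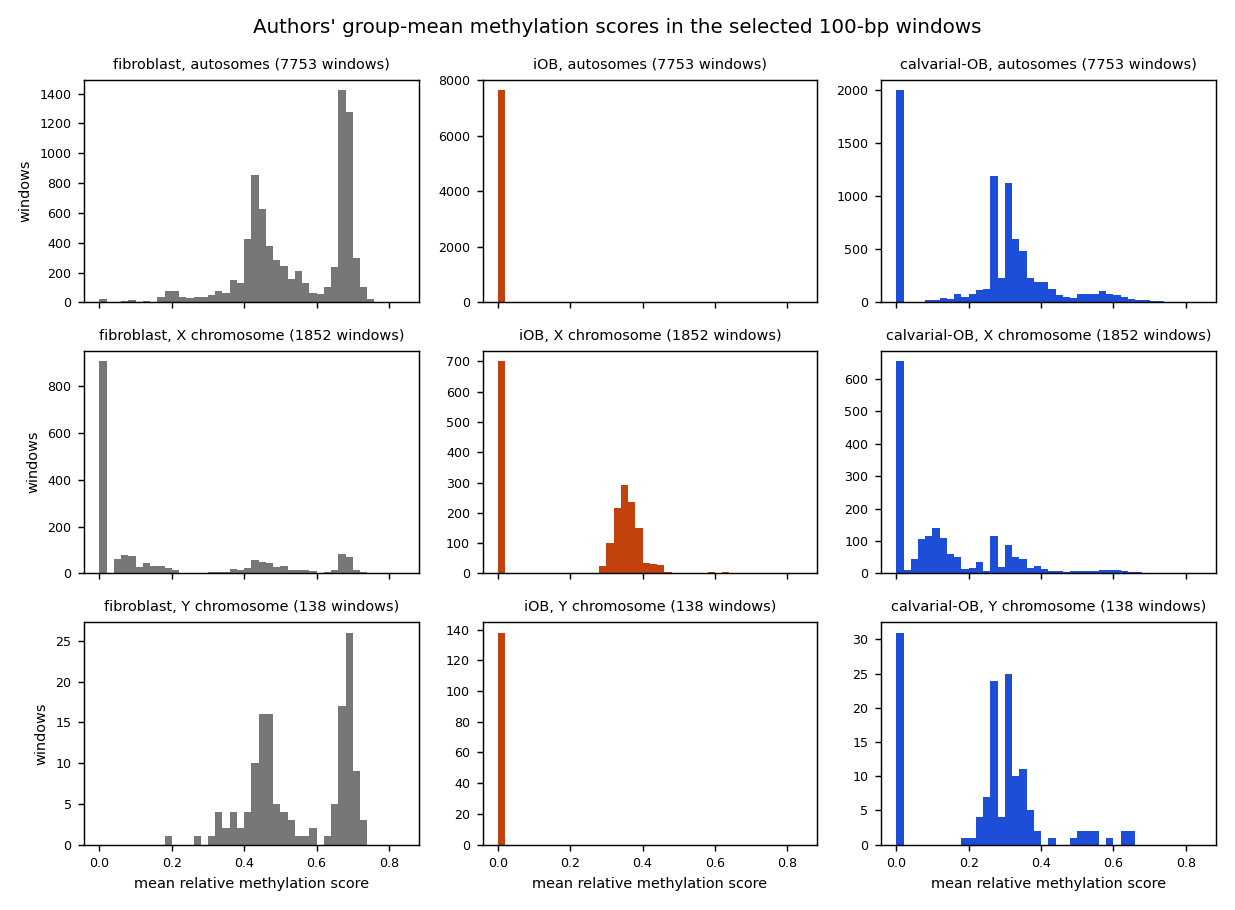
Number of windows (vertical axis) by group-mean relative methylation score (horizontal axis, without unit) for fibroblast, iOB and calvarial-OB in columns and for autosomes, X and Y in the 3 lines of panels. On autosomes 98.4% of iOB scores are 0, while on X the windows that gained score have a mean of 0.360 in iOB.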

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

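All tests in this part were chosen after the results were seen, except the comparisons of groups. The comparisons with fibroblasts picked out 455 genes called in opposite directions, 293 higher in iOB and lower in calvarial-OB and 162 the reverse; in the direct comparison all 455 differed, which calls in opposite directions against the same libraries nearly ensure. Among them, the coagulation factor gene F5 stood at 8.80 CPM in fibroblasts, 118 in iOB and 0.296 in calvarial-OB (1, 2 and 8 counts; log2 fold change between iOB and calvarial-OB 8.37, or 9.24 without calvarial-OB replicate 3), and Flt4, a receptor gene of lymphatic endothelium, at 6.26, 38.0 and 0.165. The direct comparison picked out lists whose effect against fibroblasts differed between these groups: the listed factors, with a median log2 fold change of 2.70 in iOB against calvarial-OB, adipocyte genes, with -2.24, and posterior Hox genes, with 8.08 as fitted and 6.33 with genes without counts at their bound. The 4 factors are listed as delivered from knowledge of the study and not from the labels, tail and skull cells differ in position, and dataset and Xist expression differed as well. For posterior Hox genes delivery is argued against, since the median against fibroblasts was already -6.46 in calvarial-OB and only -0.25 in iOB. Adipocyte genes had medians against fibroblasts of 3.53 in calvarial-OB and 1.39 in iOB, where 12 of 15 were higher and 2 lower. The list thus did not lie below the fibroblast level in unsorted iOB. Without a control for virus and medium, this does not show what delivery alone did. In GFP+ cells 1 of 16 adipocyte genes was higher and 1 lower, and 7 had no adjusted p (cameraPR adjusted p = 0.98). Otherwise these sources cannot be told apart.

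Macrophage genes were higher than in fibroblasts in both osteoblast groups. TMM normalization holds the median log2 fold change of all tested genes near 0, here -0.036, so that value alone tests nothing. A shift in library scaling would move all genes alike, however, and could not set the list, with a median of 5.71, apart from them. Macrophages in the cultures may account for the pattern, but this was not decided. The 18 genes differed between iOB and calvarial-OB with an SD of 0.753, against 1.56 for 308 other genes at least 16-fold higher in both groups. A share of 0.0109 of 10000 random draws had an SD as small. Genes induced together could give as small an SD, and the draws were not matched for expression or correlation, so the SD does not separate these causes. Induction in reprogrammed cells stays open, since the fold changes in GFP+ cells were lower than in unsorted iOB by a median difference of -1.72 but 17 of the 18 genes had no p there, larger standard errors (0.622 to 1.08 against 0.273 to 0.587) would lower moderated values, and sorting would remove other cells. The abundant macrophage gene Lyz2 reached 1378 to 2204 CPM in iOB and 17.6 to 47.0 in fibroblasts, and no gene of the list is in another list.

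Of the windows that gained score in iOB, 94.0% lay on the X chromosome. Depth or enrichment of the iOB libraries was not decided: windows with a fibroblast score of 0, of which 97.5% lay on X, are listed only because another group was higher, so their share restates the pattern and argues neither way. Female cells in the iOB methylation libraries could give such a pattern and would leave no signal on Y. All 138 Y windows were at 0. At the autosomal share of scores above 0 this had a chance of 0.102 if windows were independent. They are not independent and were selected on these samples, so this value decides nothing and female cells stay open. X-linked gain during reprogramming stays open too: the largest Xist count in an iOB RNA library was 1, yet whether RNA and methylation libraries came from the same cultures is not stated.

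Autosomal iOB scores were 0 in 98.4% of windows. Over all X windows 62.3% had an iOB score above 0, but among windows with a fibroblast score at or above the median the share was 1.63% on X (95% interval 0.531 to 3.76) and 1.20% on autosomes (0.899 to 1.56). All of these windows were lower in iOB, so their selection leaves lower depth or enrichment as the whole cause open. Loss of methylation may contribute, with a mean autosomal iOB score of 0.00547 against 0.543 in fibroblasts, but group means of windows selected on these samples cannot decide it.

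For each comparison of 2 groups, the 6 libraries can be divided in 10 ways, too few for a share under 0.05. In fits of 2 groups the real division gave 6957 genes for iOB against fibroblast, 6790 for calvarial-OB against fibroblast and 5816 for iOB against calvarial-OB, each reached by 1 of 10 divisions, and the highest of the others gave 0.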

How the results depend on the processing

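Leaving out Rn45s, the X chromosome alone, windows with an iOB score above 0, and leave-one-out for lists and overlaps were chosen after the data were seen. Of 3077 comparisons of 237 gene results, 3051 kept their side of the threshold, and 23 lost and 3 gained a call, in 9 results. A change of sign with a call in either fit occurred in 0. Changes of sign between uncalled values were counted as kept, and stricter thresholds were not among these comparisons. The genes were named largely for a small adjusted p or a large fold change, which favours keeping a call. Requiring a log2 fold change of at least 1 left 2581, 3265 and 2607 genes for iOB against fibroblast, calvarial-OB against fibroblast and iOB against calvarial-OB, 3387 for GFP+ cells, 1544 shared and 103 opposite genes, and 1702 shared by GFP+ and unsorted iOB; a threshold of 0.01 left 2397 shared and 218 opposite. These follow from stricter thresholds. With an estimated correlation 3, 4 and 3 lists were called, and on genes at or above the median expression 9 for calvarial-OB against fibroblast, where fewer genes were tested. The authors' iOB table at a base mean of at least 100 gave 3717 genes. The percent of windows lower in iOB, lower in calvarial-OB and nearer calvarial-OB was 98.5, 98.0 and 98.9 at calvarial-OB differences at or above the median, 95.3, 88.5 and 90.2 with windows within 1 kb merged, 98.9, 87.1 and 87.2 on autosomes, and 32.5, 36.4 and 59.99 on X; 54.0 were nearer where iOB was above 0. The cause was not tested. Counts without 1 library ranged from 4717 to 5125, 6580 to 7825 and 5435 to 7205 genes, 12 to 13, 12 to 14 and 11 to 13 lists, 2872 to 3889 shared and 304 to 660 opposite genes. The counts of 7825, 7205, 3889 and 660 were all reached without calvarial-OB replicate 1. DESeq2 gave 5577, 7451 and 6382 genes. Replicate numbers did not pair libraries, as 3 of 9 correlated best with their own number, and with that number as a block 5614, 7364 and 6303 genes were called; the keratinocyte list lost its call for iOB against fibroblast, and collagens there, skeletal muscle for calvarial-OB against fibroblast and chondrocyte for iOB against calvarial-OB gained one (camera adjusted p = 0.053, 0.038, 0.036 and 0.034). Upper-quartile normalization shifted higher and lower counts to 4397 and 3166 for calvarial-OB against fibroblast and 2912 and 3789 for iOB against calvarial-OB. No paired analysis was possible for GFP+ cells because the table holds no values per library, which also ruled out leave-one-out and an estimated correlation there. Not run were 3 alternatives for methylation against expression, a stricter p for windows, and the bone chip comparison, for want of an mm9 annotation, of p values and of values. Depth and spread limit small changes: a 1.5-fold change was recovered for 8.96%, 22.4% and 25.4% of simulated genes in the 3 comparisons.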

Other observations

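All tests in this part were chosen after the results were seen, except the list tests, and single genes outside the naming rule were chosen after their values were seen. Among DNA methylation enzymes, a list not called in iOB against fibroblast (3 of 16 higher, 5 lower; camera adjusted p = 0.73), the maintenance genes Uhrf1 and Dnmt1 fell by 1.63 ± 0.23 and fell by 0.55 ± 0.11, and the de novo methyltransferase gene Dnmt3a rose by 0.93 ± 0.16 (edgeR adjusted p = 1.5e-04, 0.0022 and 5.8e-04). In iOB against calvarial-OB the list had 7 lower and none higher, or 6 lower adjusted over the list alone (camera adjusted p = 0.095). The Notch target gene Heyl rose by 4.46 ± 0.21 in calvarial-OB against fibroblast and fell by 3.40 ± 0.20 in iOB against calvarial-OB, within a Notch and hedgehog list that was not called in any comparison (camera adjusted p = 0.73, 0.70 and 0.94). S100b and Nes, of neural and glial cells, rose by 4.15 ± 0.19 and 1.77 ± 0.19 in calvarial-OB against fibroblast.

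Of 18 posterior Hox genes 6 were lower and 2 higher in iOB against fibroblast, and the list was not called (camera adjusted p = 0.14): Hoxb13 fell by 1.04 ± 0.15 and Hoxb9 fell by 0.80 ± 0.12. Other lists not called there were collagens (12 of 29 higher, 8 lower), chondrocyte (9 of 20 and 6), contractile (6 of 14 and 3), matrix remodelling (9 of 26 and 8), inflammatory (5 of 16 and 6), endothelial (2 of 7 and 2), skeletal muscle (2 of 6 and 1), anterior Hox (1 of 9 and 0), cranial mesenchyme (3 of 19 and 2), immediate early (10 of 20 and 2), pluripotency (2 of 3 and 0), neural (4 of 8 and 0) and Notch and hedgehog (6 of 15 and 1). Median, mean and camera's direction differed in sign for the contractile, matrix remodelling, inflammatory, endothelial and cranial lists there. Adjusted over the list alone, 13 collagens, 3 skeletal muscle, 12 immediate early and 5 neural genes were higher and 3 endothelial and 3 immediate early genes lower, and the other counts were the same. Signs also differed for the inflammatory, endothelial and Notch and hedgehog lists in calvarial-OB against fibroblast, and for the contractile, inflammatory and Notch and hedgehog lists in iOB against calvarial-OB. A list of erythroid and lymphoid genes had tested members in GFP+ cells only (1 of 8 higher, 1 lower). In calvarial-OB against fibroblast, interferon genes (7 of 25 higher, 3 lower; 6 and 3 adjusted over the list alone) and Wnt genes (17 of 29 higher, 8 lower) were not called.

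The lower Slc16a3, Bnip3 and Ndufa4l2 in iOB raised the hypothesis of a weaker hypoxia response. A hypoxia list was written after these genes and Ak4 had been seen, without them. Of its 24 tested genes 17 were lower and 1 higher, with a median log2 fold change of -1.09 (camera p = 6.6e-12), but with an estimated correlation p was 0.0796, so a weaker hypoxia response may or may not be present.

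Xist had 0, 1 and 2 counts in the fibroblast libraries, 1, 1 and 0 in iOB and 341, 186 and 2211 in calvarial-OB, and the Y-linked gene Ddx3y stood at 65.7 to 128 CPM across the 9 libraries.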
